A study of Mus musculus with 4 samples.

How the data were processed

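Kidneys of 2 groups of mice with I/R injury, labelled IRD7 and IRR300, were measured by single-cell RNA sequencing and by spatial RNA sequencing of sections, 1 library per group and method. Per the labels, kidneys for the single-cell libraries were dissociated with enzymes, red cells were lysed, dead cells were removed where viability was under 85%, and at least 20000 cells were applied per sample. The deposited matrices hold raw UMI counts per gene and barcode with no normalisation; per the file headers they were written by Cell Ranger 7.0.0 (single cells) and Space Ranger 2.0.0 (sections). The submitters' notes instead name Cell Ranger 3.1.0, Space Ranger 2.0.1, Seurat 4.3.0, R 4.2.2 and the mouse build mm10, and which of these made the matrices was not settled. Each matrix lists 32285 genes, the same in all 4 libraries. Gene positions came from a GRCm38 annotation, to which 32158 of the genes (99.6%) were matched. Spot positions and sham kidneys were not used here.

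Cells were kept with at least 500 UMIs, at least 200 genes and at most 50% mitochondrial UMIs, which left out 427 IRD7 and 501 IRR300 barcodes over the mitochondrial limit. Doublets were called per library with scrublet in scanpy, 160 (1.53%) and 316 (2.74%), and removed. Cells of both libraries were scaled to 10000 counts, log-transformed and clustered together without integration, on 2000 variable genes, 30 principal components and 20 nearest neighbours, with Leiden at resolution 1.0 and seed 0. The 36 clusters were named from 24 sets of marker genes. A set had to reach a mean score of 1.5 with at least 3 markers found in at least 10% of the cells at 2-fold or more, and a cluster stayed unnamed where another set reached 0.8 of the best score, where another class had more markers among the 10 leading genes, or where depth was low and no own marker led. Fibroblasts, pericytes and smooth muscle were merged as stromal-like, and T cells with NK cells. Names are therefore classes by RNA, not sorted cells. Spots were clustered in the same way without a mitochondrial limit or doublet calls.

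Counts were summed per library over the cells of a class or the spots of a section, scaled to CPM and compared as ratios of IRR300 over IRD7. Each ratio had an exact conditional binomial 95% interval, each share an exact Clopper-Pearson interval and each ratio of shares an exact conditional interval. A gene with fewer than 3 counts in the lower library was set to a floor of 3 counts. Since 1 library stood for each group, no p-value, no number of differing genes and no replicate check could be given, and the intervals say nothing of variation between mice. Cycling cells were those with at least 2 of the proliferation genes after thinning each cell to 1000 UMIs, which left out 25 IRD7 and 4 IRR300 macrophage-like cells with too few UMIs. Co-location used Spearman correlations across spots thinned to 3000 UMIs, and agreement used genes with at least 50 counts.

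The 18 gene lists were proliferation, alternative activation, classical activation, fibrosis-associated macrophage, thrombospondin axis, platelet, extracellular matrix, tubular injury, proximal tubule transport, fatty acid oxidation, interferon response, chemokines, antigen presentation, glycolysis and hypoxia, dissociation stress, erythroid, endothelial, and coagulation and complement. A list was summarised by the median log2 ratio of members with at least 10 counts, with an exact binomial interval of the median, and its place among 10000 random lists matched in 20 bins of expression. Some genes are in 2 lists: Spp1, Vegfa, Fn1, Cxcl10 and Ccl2.

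Genes were named by a fixed rule. In classes with at least 100 cells per library and in the sections, genes with at least 30 counts and 50 CPM in the higher library were ranked by the interval bound nearest 1. In classes a gene also needed at least the level of all other cells of that library. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked and unnamed transcripts were left out. The 10 highest and 10 lowest were named for macrophage-like and proximal tubule-like cells and for the sections, and 5 and 5 for stromal-like and endothelial-like cells; a few genes that this rule picks are not reported here. Of each list 2 to 4 members with the most counts were named where useful, and 12 genes were named throughout: Thbs1, Cd36, Cd47, Mki67, Top2a, Mrc1, Arg1, Spp1, Col1a1, Havcr1, Lcn2 and Pf4. Cluster and region leaders, and single genes of the tests in the closing part, fall outside the rule and were chosen after their values were seen.

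The lists, marker genes, measures, naming rule and most alternatives were set before the data were examined. The thresholds for naming clusters, the merging of stromal types and 9 further alternatives were chosen afterwards. Those 9 were macrophages without the proliferation-led cluster, macrophages of at least 4000 UMIs, macrophage share among immune cells, cycling without S phase genes, cycling of macrophages and monocytes together, the proximal tubule with the Havcr1-led cluster, the proximal tubule as shared clusters only, sections without fat and blood spots, and sections within the leading tubule segment. The alternatives set earlier covered doublets kept, a 25% mitochondrial limit, at least 500 genes per cell, resolution 2.0, each library clustered on its own, size factors in place of totals, other thinning depths and other count minimums. Size factors moved the median of all genes by over 0.1 only in proximal tubule-like cells, by -0.19 on the log2 scale.

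The interval was tested on simulated Poisson counts at each comparison's own depth. Poisson error is what the interval assumes, so coverage near 95% was built in. Variation between cells or mice was not simulated. Among 15732 genes of macrophage-like cells the interval held the true ratio for 96.0% of unchanged genes. It found the right side for 77.3%, 81.5% and 95.2% of genes set at 1.5-fold, 2-fold and 4-fold. For proximal tubule-like cells (17263 genes) these were 95.6%, 66.2%, 87.9% and 95.3%, and for stromal-like cells (16580 genes) 95.8%, 78.1%, 77.3% and 95.4%. For endothelial-like cells (12672 genes) they were 95.9%, 50.7%, 74.2% and 95.2%. For the sections (18045 genes) they were 95.4%, 83.3%, 84.4% and 100%. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9.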

Results

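Kidneys of mice with acute injury from bilateral ischaemia-reperfusion (I/R) were profiled in 4 libraries. One group is labelled IRD7. In the other, labelled IRR300, I/R was followed, as the series design reads, by injection of R300, an antibody that depletes platelets. Each group had 1 library of dissociated single cells and 1 library of spatially barcoded spots of a kidney section. Kidneys after sham surgery were not analysed here. The time after injury was not spelled out for either group, so a difference in time was not parted from one in treatment. The IRD7 single-cell library held 131403603 unique molecular identifiers (UMIs, tags that mark single RNA molecules) in 10905 barcodes, of which 10318 were kept, with a median of 9046 UMIs per cell. Its IRR300 counterpart held 136464406 UMIs in 12030 barcodes, of which 11213 were kept, with a median of 8806. The IRD7 section gave 77412029 UMIs in 4284 spots and the IRR300 section 73621980 UMIs in 3990 spots, with medians of 16876.5 and 15007 UMIs per kept spot. With 1 library per group there was no replicate error, so no test between groups was made. Intervals are 95% intervals, and those of genes and shares are exact and cover counting error only. Those of list medians cover the spread over list members, and those of correlations rest on the number of spots or genes. Every difference below is one between libraries. Levels are UMI counts scaled to the total of the library or class (CPM), and ratios are IRR300 over IRD7.

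The first comparison asked which cell types made up the dissociated kidneys of each group. Tubule cells, immune cells, stromal cells and vessel cells were all recovered. The IRR300 library held relatively more proximal tubule and neutrophil cells and relatively fewer monocytes, stromal cells and T and NK cells. Proximal tubule-like cells, the epithelium most exposed to ischaemic harm, made up 23.97% of IRD7 cells (23.1 to 24.8) and 31.9% of IRR300 cells (31.1 to 32.8). Macrophage-like cells made up 19.3% (18.5 to 20.1) and 21.9% (21.2 to 22.7), a ratio of 1.14 (1.07 to 1.21). This small difference moved with the clustering, and the ratio was 1.55 when each library was clustered on its own and 1.07 (0.999 to 1.14), no longer clear of 1, at a finer clustering. Neutrophil-like cells made up 7.34% and 13.4%, a ratio of 1.82 (1.67 to 1.99). Monocyte-like cells were 3.34-fold less frequent in the IRR300 library, at 9.06% against 2.71%. Stromal-like cells, which hold fibroblasts, pericytes and smooth muscle, were 2.09-fold less frequent, at 12.4% (11.8 to 13.1) against 5.97% (5.53 to 6.42). The share of T and NK-like cells was 2.17-fold lower, at 3.91% against 1.80%, and that of endothelial-like cells 1.66-fold lower, at 2.68% against 1.61%. The endothelial difference hung on naming, since a cluster led by endothelial genes such as Cdh5, but unnamed because it also carried stromal markers, held 59 IRD7 and 195 IRR300 cells.

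Among the other tubule and epithelial classes, the share ratio was 0.820 (0.695 to 0.967) for loop of Henle-like cells, 0.640 for collecting duct principal-like cells and 0.577 for urothelium-like cells. For collecting duct intercalated-like cells the ratio was 0.868 and its interval of 0.680 to 1.11 included 1, as did that of B cell-like cells at 1.21 (0.854 to 1.71). Podocyte-like cells were few, 32 against 103, at 0.310% and 0.919%. Cells left unnamed made up 12.1% and 12.97%; they included a cluster led by the injury genes Havcr1 and Krt20, which carried markers of more than one epithelium and held 274 and 313 cells. Shares sum to 100% within a library and depend on dissociation, so a lower share is not a lower number in the kidney. Within the proximal tubule-like class, the cluster led by Pdk4 and Cyp4b1 held 345 IRD7 and 1758 IRR300 cells, whereas the largest of the others held 1061 and 691.

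**Figure D1:**
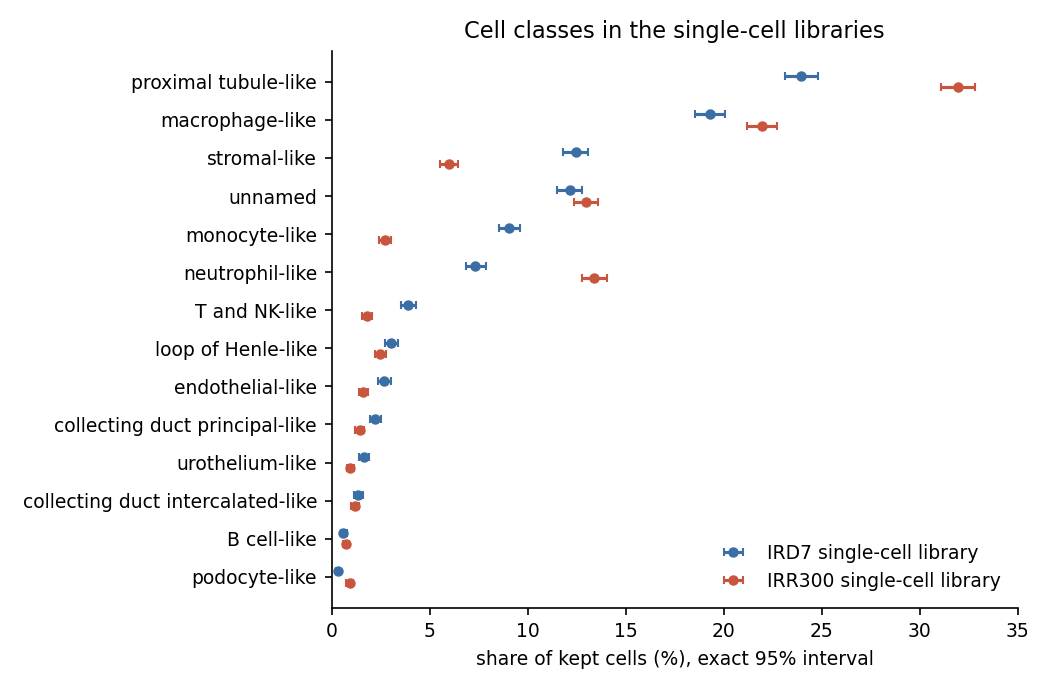
Share of kept cells in each cell class (percent, horizontal axis) in the IRD7 and IRR300 single-cell libraries; points are shares and bars exact 95% intervals. The stromal-like share was 12.4% in IRD7 and 5.97% in IRR300 cells, and the neutrophil-like share 7.34% and 13.4%.

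The study's title names cycling macrophages fuelled by platelets, so the share of macrophages in the cell cycle was compared. Cycling macrophages formed a sizeable part of the IRD7 macrophages and a very small part of those in the IRR300 library. A cell was called cycling when at least 2 of 25 proliferation genes were detected after each cell was thinned to 1000 UMIs. By this measure 318 of 1966 IRD7 macrophage-like cells were cycling, or 16.2% (14.6 to 17.9). In the IRR300 library the number was 20 of 2455, or 0.815% (0.498 to 1.26), which gave a ratio of 0.0504 (0.0303 to 0.0791). One macrophage cluster was led by Hist1h2ap, Top2a and Mki67, and it held 288 IRD7 and 16 IRR300 cells. The share depended on how many genes were asked for, since 98 IRD7 cells had 2 of the genes and 231 had 1, against 8 and 165 IRR300 cells. With 1 gene asked for the ratio was 0.296, with thinning to 2000 UMIs it was 0.0936, and without thinning it was 0.336, at 44.5% and 14.97%.

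Neutrophils do not divide once mature and gave the background of the measure. Their cycling share was 0.404% in the IRD7 and 0.470% in the IRR300 library, so the IRR300 macrophage share of 0.815% lay close to background. Without thinning, 3.70% and 1.93% of neutrophil-like cells had at least 2 of the genes. Macrophage-like cells called cycling had a median of 14249.5 UMIs in the IRD7 and 15159.5 in the IRR300 library, and the other macrophage-like cells 10183.5 and 9778. Fewer cycling cells were also seen outside macrophages. T and NK-like cells were cycling in 73 of 400 cases (18.3%) against 5 of 201 (2.49%). Stromal-like cells were cycling in 170 of 1214 cases (14.0%) against 10 of 624 (1.60%), and proximal tubule-like cells in 86 of 2370 (3.63%) against 21 of 3468 (0.606%). Of collecting duct principal-like cells, 21 of 229 (9.17%) were cycling in the IRD7 library and 0 of 160 in the IRR300 library, which allows a share of up to 1.88% by a limit of 3 counts and 2.28% by the exact interval. Over all cells outside the macrophage-like class the ratio was 0.147 (0.112 to 0.190), above the interval of the macrophage ratio. The stromal-like ratio of 0.114 (0.0539 to 0.216) and the T and NK-like ratio of 0.136 (0.0430 to 0.333) overlapped that interval, while the proximal tubule-like ratio of 0.167 (0.0983 to 0.271) lay above it.

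**Figure D2:**
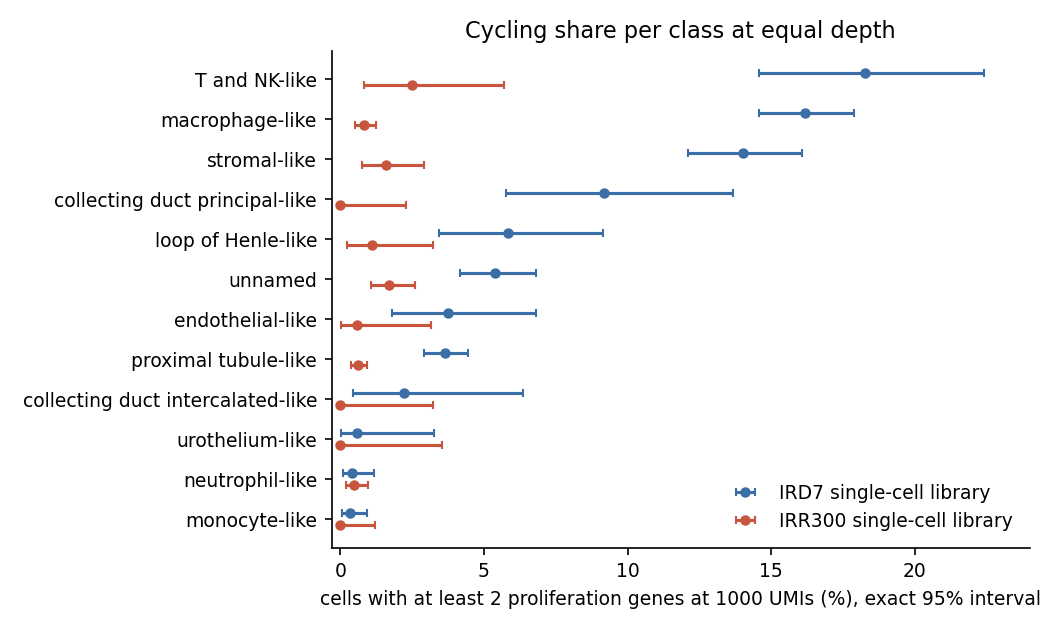
Share of cells with at least 2 proliferation genes detected at 1000 UMIs (percent, horizontal axis) per cell class in the IRD7 and IRR300 single-cell libraries; points are shares and bars exact 95% intervals. Macrophage-like cells sat at 16.2% and 0.815%, and neutrophil-like cells at 0.404% and 0.470%.

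The macrophage-like cells of both libraries were next compared gene by gene, with counts summed over 1991 IRD7 and 2459 IRR300 cells. In the IRR300 library these macrophages carried less RNA of the cell cycle, of the interferon response and of antigen presentation. Thrombospondin 1 RNA was higher. Alternative and fibrosis-associated activation genes were mixed. All 25 proliferation genes were lower in the IRR300 library, with a median log2 ratio of -3.87 (-4.25 to -3.30), which lay below all 10000 random lists matched on expression. Among them Top2a, a topoisomerase needed in dividing cells, stood at 146 against 12.7 CPM, and Mki67, the proliferation antigen Ki-67, at 119 against 22.6 CPM. Without the proliferation-led cluster the median was -2.58 and Mki67 lay at -0.63 in place of -2.40. Of the replication-dependent histone genes, Hist1h2ap was 49.9-fold lower (253 against 5.07 CPM), Hist1h2ae 18.0-fold and Hist1h1b 17.4-fold. Birc5, which encodes survivin, was 21.3-fold lower, and Ube2c, a mitotic ubiquitin-conjugating enzyme, 20.6-fold.

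Interferon response genes were lower in all 14 measured cases, with a median of -2.66 (-3.81 to -1.67). The GTPase gene Gbp2, induced by interferon gamma, was 47.4-fold lower (271 against 5.71 CPM). The related Ifi47 was 14.0-fold, Gbp3 13.4-fold and the membrane tether gene Bst2 2.03-fold lower. Antigen presentation genes were lower in 12 of 12 cases, with a median of -1.35 (-1.77 to -0.57). Cd74, the invariant chain of class II molecules, had 2226 CPM in the IRD7 and 898 CPM in the IRR300 library, and B2m, the light chain of class I, 2003 and 1348 CPM. Histone, Gbp, Tgtp, Cyp4a and Serpina1 genes have close relatives in the genome, so the split of reads between relatives is uncertain wherever they are named.

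Apoc1, an apolipoprotein gene, was the gene most clearly higher in IRR300 macrophages, at 9.16 against 82.4 CPM, a ratio of 8.99 (7.80 to 10.4). Gpnmb, a glycoprotein of lysosome-rich macrophages, stood at 83.1 against 414 CPM, a ratio of 4.98 (4.74 to 5.23). Gpnmb, Arg1, Apoc2, Fabp5 and Mmp19 were leading genes of a macrophage cluster that held 470 IRD7 and 837 IRR300 cells, so their ratios include a shift between clusters. Thbs1 encodes thrombospondin 1, a matrix protein that platelets also carry in their granules. Its level was 548 CPM in IRD7 and 1603 CPM in IRR300 macrophages, a ratio of 2.93 (2.87 to 2.98). Ratios of 3.40 for the metalloproteinase gene Mmp19, 3.25 for the chemokine receptor gene Cxcr4 and 2.89 for Atp6v0d2, a proton pump subunit, were also among the 10 highest. The lipoprotein lipase cofactor Apoc2 (2.58), the fatty acid binding protein Fabp5 (2.48), the surface receptor Cd93 (2.54) and the ubiquitin ligase subunit Fbxo32 (2.79) completed them. The thrombospondin axis list, thrombospondin 1 and its receptors, was higher in 8 of 12 genes with a median of 0.32 (-0.10 to 0.64). Its receptor Lrp1 had a ratio of 1.90, Cd36 1.41 (1.35 to 1.48) and Cd47 0.878 (0.847 to 0.911).

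Alternative activation genes were higher in 9 of 15 cases with a median of 0.19 (-0.50 to 0.44); Arg1, the enzyme arginase 1, had a ratio of 1.80 and Mrc1, the mannose receptor, 1.499. Fibrosis-associated macrophage genes were higher in 10 of 14 cases with a median of 0.16 (-0.08 to 0.83). There the secreted phosphoprotein gene Spp1 differed little, at 4297 against 4635 CPM, and its log2 ratio of 0.11 turned to -0.06 without the proliferation-led cluster. Classical activation genes were lower in 9 of 13 cases with a median of -0.46 (-2.46 to 0.12), yet Il1b, their most abundant member, was higher with a ratio of 2.09. Chemokine genes were lower in 12 of 16 cases with a median of -0.24; Ccl4 had a ratio of 0.635 and Ccl6 one of 1.49. The platelet list had 6 measured genes, 3 of them higher. Its signal came from Pf4, a chemokine gene of platelets and of some macrophages, at 947 against 1168 CPM, while the platelet gene Ppbp was at 2.05 against 1.93 CPM. Matrix genes were low in these cells and lower in 18 of 20 cases, with Col1a1 at 64.1 against 26.0 CPM, much as in classes that do not make matrix. Havcr1 did not differ within counting error (0.629 to 1.27), and Lcn2 had a ratio of 0.838. Lists without a clear side were glycolysis and hypoxia (-0.16), dissociation stress (-0.07), fatty acid oxidation (-0.06), tubular injury (-0.20) and proximal tubule transport (0.10).

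**Figure D3:**
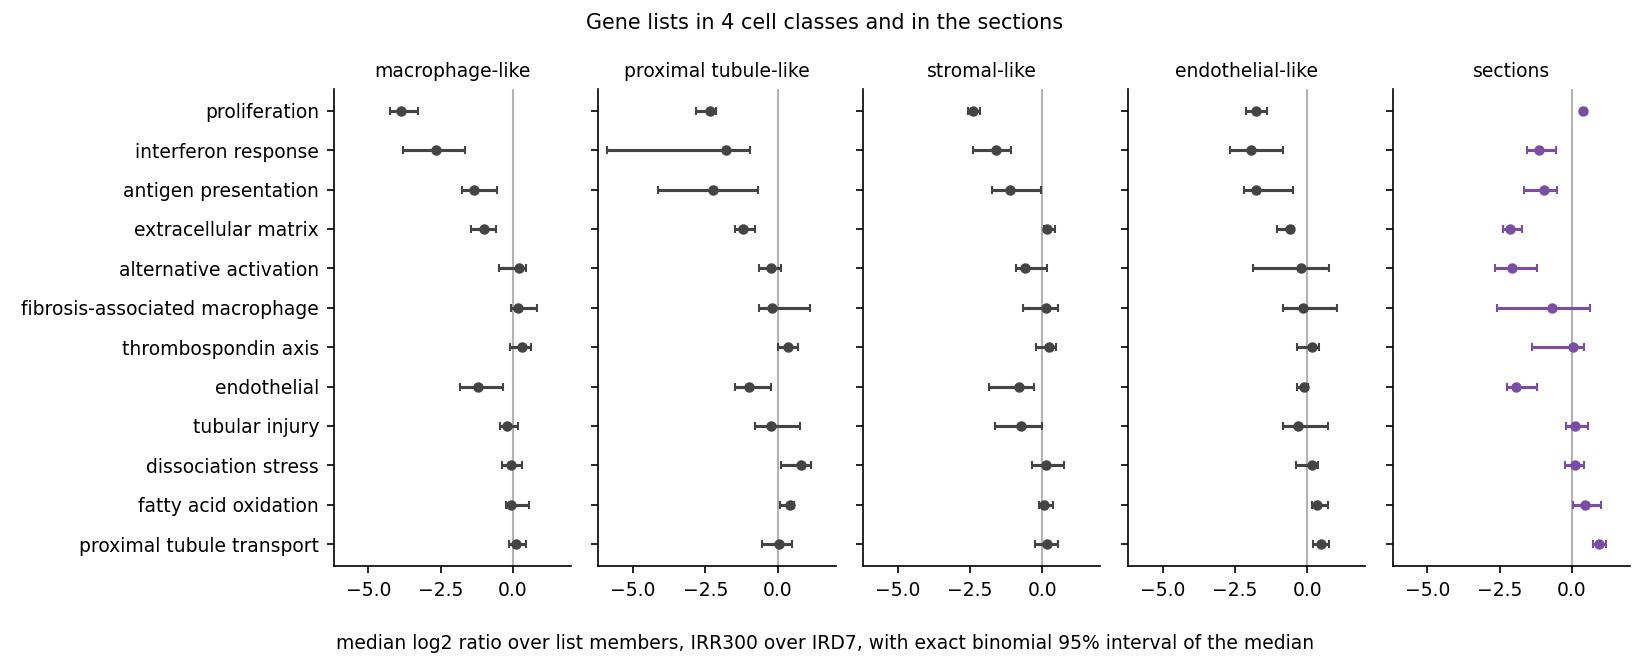
Median log2 ratio, IRR300 over IRD7, of 12 gene lists (horizontal axis) in macrophage-like, proximal tubule-like, stromal-like and endothelial-like cells and in the sections; points are medians over list members and bars exact binomial 95% intervals of the median. Proliferation lay at -3.87 in macrophage-like cells and at 0.40 in the sections.

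Proximal tubule cells reabsorb most of the filtrate, burn fatty acids and are the main target of ischaemic harm, so they were compared next. In the IRR300 library they carried less RNA of interferon response genes. Fatty acid oxidation genes were slightly higher, by a margin that depended on the scaling. Transport genes showed no common direction, and injury genes were mixed. Counts were summed over 2473 IRD7 and 3582 IRR300 cells. Cyp4a14 and Cyp4a10, which hydroxylate fatty acids, had ratios of 6.81 (6.66 to 6.96) and 4.08 (3.96 to 4.21). Fatty acid oxidation genes were higher in 14 of 15 cases with a median of 0.41 (0.09 to 0.56), at percentile 97.0 of the random lists. The interval reached no difference with size factors, at 0.22 (-0.09 to 0.37), and with mitochondrial and ribosomal genes left out of the total, at 0.31 (-0.0036 to 0.46). The median was 0.26 in the clusters shared by both libraries. The peroxisomal enzyme Ehhadh had a ratio of 3.06, while Acsm2 was 1.86-fold lower. Txnip, which binds thioredoxin, and Pdk4, which holds back glucose oxidation, had ratios of 5.31 and 4.50. The mitochondrial carrier Slc25a25 (5.82), the cytochrome P450 gene Cyp2a5 (5.57), the chloride channel Cftr (4.71), the collagen-modifying enzyme P3h2 (4.09) and BC035947 (4.55) were also among the 10 highest.

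These levels depended in part on which tubule cells each library held. In the clusters that held over 500 cells of both libraries, the log2 ratio was 2.59 for Cyp4a14 (2.77 in all cells of the class). It was smaller for Txnip (1.44 against 2.41), Pdk4 (0.98 against 2.17), Slc25a25 (1.57 against 2.54), Cyp2a5 (1.72 against 2.48), Cftr (1.07 against 2.24), BC035947 (1.07 against 2.18) and P3h2 (1.13 against 2.03). Havcr1, which encodes the injury molecule KIM-1, had 44.3 and 57.0 CPM, a ratio of 1.29 (1.21 to 1.37). That direction turned in those clusters, where its log2 ratio was -0.80. The tubular injury list was higher in 7 of 18 genes with a median of -0.22 (-0.80 to 0.78). Its member Spp1 was 3.67-fold lower (10166 against 2773 CPM), the keratin gene Krt8 higher with a ratio of 3.27, and Lcn2 had a ratio of 0.912. Proximal tubule transport genes were higher in 8 of 15 cases with a median of 0.06 (-0.53 to 0.48). The phosphate carrier Slc34a1 was 1.98-fold lower, the anion carrier Slc22a6 had a ratio of 1.66 and the endocytic receptor Lrp2 one of 1.09, whose log2 ratio turned to -0.061 with size factors and -0.092 in the shared clusters.

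Interferon response genes were lower in 13 of 14 cases in these cells, with a median of -1.80 (-5.90 to -0.96). The immunity-related GTPase gene Iigp1 was 345-fold lower, at 415 against 1.20 CPM. Its relatives followed, with Tgtp1 264-fold, Igtp 59.9-fold, Irgm2 26.3-fold and Irgm1 17.5-fold lower; Igtp and Irgm2 overlap on the same strand of chromosome 11, so their reads are hard to part. Gbp6 was 187-fold, Gbp7 24.6-fold, Tmem140 9.64-fold and the fatty acid binding protein Fabp7 5.06-fold lower. All 12 antigen presentation genes were lower (median -2.24), Cd74 by 3.70-fold. Proliferation genes were lower in 25 of 25 cases (median -2.35), Mki67 at 31.9 against 3.88 CPM and Top2a at 24.3 against 1.962 CPM. Dissociation stress genes were higher in 13 of 14 cases with a median of 0.79 (0.13 to 1.14), which was 0.11 in the clusters shared by both libraries; Jun had a ratio of 2.09 and Fos 2.20. Cd36, a fatty acid transporter and thrombospondin receptor, had a ratio of 4.402 and Cd47 0.926, though the log2 ratio of Cd47 turned to 0.063 in the shared clusters. Thbs1 had a ratio of 1.53 (1.40 to 1.67) at only 21.1 against 32.1 CPM, where free RNA of other cells was not parted from that of the tubule. Thrombospondin axis genes were higher in 10 of 12 cases (median 0.36), among them Sdc4 at 1.61 and Calr at 1.43. Intervals for Mrc1 and Arg1 included 1, and Pf4 had a ratio of 0.752. Matrix genes were lower in 19 of 20 cases (median -1.21), Col1a1 at 58.7 against 24.9 CPM. Medians of -1.37, -1.28 and -1.32 in monocyte-like, neutrophil-like and T and NK-like cells lay near it, so these counts were read as background and not as tubule expression.

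Stromal cells make the matrix of the scarring kidney, and the title names fibrosis, so the stromal-like class was compared next. As a part of all its RNA, matrix RNA differed little between the libraries, although the class itself was a smaller part of the IRR300 library. Renin RNA was higher, while cell cycle and interferon genes were lower. Counts were summed over 1284 IRD7 and 669 IRR300 cells, whose make-up differed. A cluster led by Mgp and Cxcl14 held 697 and 204 cells, one led by Postn, Tnfaip6 and Lum 281 and 363, and one led by proliferation genes 57 and 0, so ratios of the class mix subtypes. Extracellular matrix genes were higher in 15 of 20 cases, with a median of 0.15 (0.06 to 0.42), at percentile 95.7 of the random lists. In the simulated counts of this class, medians of unchanged lists lay up to 0.19 from 0, so so small a median was not told from no change. Col1a1, the main chain of fibrillar collagen, stood at 6062 against 7358 CPM, a ratio of 1.21 (1.20 to 1.23). Col1a2 had a ratio of 1.34, Col3a1 1.07 and Sparc, a matrix-binding glycoprotein, 1.08. Ren1, the renin gene of juxtaglomerular cells, stood at 64.6 against 1519 CPM, a ratio of 23.5 (22.2 to 24.9). A cluster led by Ren1 held 50 and 52 cells, and so a larger part of the IRR300 class. Gpnmb had a ratio of 17.4, the lipid carrier Apod 5.92, Pamr1 5.06 and the retinoic acid-making enzyme Aldh1a1 4.84.

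Proliferation genes of stromal-like cells were lower in 25 of 25 cases (median -2.41). Hist1h2ap was 23.96-fold, Cenpf 11.7-fold, Hist1h2ae 11.1-fold, Prc1 7.98-fold, Mki67 7.61-fold and Top2a 6.03-fold lower. Coagulation and complement genes were higher in 11 of 15 cases with a median of 0.60 (-0.19 to 1.00), and C3 stood at 314 against 625 CPM. Chemokine genes were lower in 11 of 16 cases (median -0.51), but the abundant Cxcl1 and Ccl2 were higher, with ratios of 3.62 and 2.13, and so was the cytokine Il6 at 3.33. Thbs1 stood at 460 against 998 CPM, a ratio of 2.17 (2.11 to 2.23). Spp1 was 2.69-fold lower, as in the tubule, and Lcn2 had a ratio of 0.588. Ratios were also below 1 for Arg1 (0.554), Mrc1 (0.766), Pf4 (0.582) and Havcr1 (0.320), all scarce in these cells; the direction of Arg1 turned when doublets were kept, to a log2 ratio of 0.05. Cd47 and Cd36 did not differ within counting error. Interferon response genes were lower in 14 of 14 cases (median -1.61) and antigen presentation genes in 10 of 12 (median -1.12), with Gbp2 3.35-fold and Cd74 2.22-fold lower.

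Vessel-lining cells meet platelets first, which was the reason to compare the endothelial-like class. Its identity genes differed little between the libraries, whereas its interferon and antigen presentation genes were lower in the IRR300 library and the adhesion molecule ICAM-1 was higher. Counts were summed over only 277 IRD7 and 181 IRR300 cells. The endothelial list was lower in 9 of 12 genes with a median of -0.10 (-0.34 to 0.02), and its sign turned to 0.11 at a finer clustering. Plvap, which spans vessel pores, stood at 1313 against 1036 CPM and the growth factor receptor Flt1 at 859 against 802 CPM. Icam1 had 143 and 352 CPM, a ratio of 2.47 (2.18 to 2.79). Acsl1, which activates fatty acids, had a ratio of 2.77, the glycine-cleaving enzyme Gldc 2.99 and the mitochondrial kinase Ak4 3.12. All other cells had like ratios for these genes, 2.70, 2.87 and 2.71, and proximal tubule transport genes were higher in 13 of 15 cases here (median 0.49), so RNA of tubule cells was not parted from that of the vessels. The lymphatic chemokine gene Ccl21a had a ratio of 4.86 (3.41 to 7.07), but this turned to a log2 ratio of -0.69 when doublets were kept, and it rested on 40 and 154 counts. Interferon response genes were lower in 14 of 14 cases with a median of -1.93 (-2.67 to -0.83). Gbp6 was 51.6-fold, Igtp 17.2-fold, Irgm2 9.45-fold and the peptide transporter Tap1 7.53-fold lower.

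All 12 antigen presentation genes of endothelial-like cells were lower (median -1.77), and proliferation genes in 20 of 22 measured cases (median -1.79). Thbs1 did not differ, at 117 against 116 CPM, a ratio of 0.988 (0.834 to 1.17). Chemokine genes were lower in 13 of 16 cases (median -0.58), while F3, which encodes tissue factor, had 67.3 and 183 CPM. Of the remaining genes fixed in advance, Lcn2 (1.56) and Mrc1 (1.68) were higher. Spp1 (0.394), Arg1 (0.186), Col1a1 (0.320), Havcr1 (0.495), Cd47 (0.831), Mki67 (0.451) and Top2a (0.263) were lower, and Cd36 and Pf4 did not differ within counting error. The finer clustering turned Spp1 to a log2 ratio of 0.19 and Flt1 to 0.09, and Spp1 had at least 382 CPM in each of the 8 classes of both libraries.

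The sections were compared as a second view of the same groups, without dissociation; a spot can hold several cells. The IRR300 section carried far less RNA of matrix, macrophages and vessels and more of differentiated tubules. Proliferation genes were slightly higher there, in contrast to the single cells. The IRD7 section also held 112 spots led by fat genes and 227 led by haemoglobin genes, against 0 and 1 in the IRR300 section. The IRR300 section held 57 spots led by fat and nerve genes such as Retn, Cidec and Npy, against 1, and 168 led by Gm42418, Lars2 and mitochondrial genes, against 0. The median mitochondrial share per spot was 2.04% in IRD7 and 7.41% in IRR300, which limits whole-section ratios. All 20 extracellular matrix genes were lower in the IRR300 section, with a median of -2.14 (-2.37 to -1.71). Col3a1 was 6.42-fold lower (2954 against 461 CPM), Fn1, the fibronectin gene, 5.93-fold, Col1a1 3.98-fold, Col1a2 3.87-fold and Col12a1 15.9-fold. Macrophage markers were lower in 9 of 9 cases (median -2.49), fibroblast markers in 8 of 8 (-2.20), endothelial markers in 9 of 9 (-1.94) and pericyte and smooth muscle markers in 8 of 8 (-1.75). Neutrophil markers lay at -0.83, T cell markers at -1.36, NK cell markers at -1.75, monocyte markers at -1.40 and podocyte markers at -0.97. On the other side were markers of the proximal tubule (1.02, 10 of 10 higher), loop of Henle (1.60, 8 of 8), collecting duct principal cells (1.44, 7 of 7), intercalated cells (0.58) and urothelium (0.62).

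Dnase1, a nuclease gene of the tubule, had the most clearly higher level in the IRR300 section, at 6.54 against 114 CPM, a ratio of 17.5 (16.0 to 19.2). Fam25c followed with 15.5, Gpx6 with 15.6 and the protease inhibitor Serpina1a with 9.89. The growth factor gene Egf (8.06) and the water channel gene Aqp2 (7.78) belong to the distal tubule and collecting duct. Acsm3 (7.79), the gluconeogenic enzyme Pck1 (5.87), the uroguanylin gene Guca2b (6.52) and the keratin gene Krt20 (6.34) were also among the 10 highest. Within spots led by the same tubule segment, Fam25c lay at a log2 ratio of 2.82 in place of 3.96. Of the 10 lowest, Cox8b, Thrsp, Cfd and Fabp4 were leading genes of the fat-led spots, and Fabp4 was also one of the endothelial-like cell cluster. In that order, these genes had log2 ratios of -8.98, -6.15, -4.24 and -4.52. Without the spots led by fat or haemoglobin genes the ratios were -5.26, -2.68, -1.15 and -2.80. That removal took out almost only IRD7 spots, since the 57 IRR300 spots led by fat and nerve genes stayed in. The chemokine gene Ccl8 was 86.1-fold lower (199 against 2.31 CPM), the macrophage lysozyme gene Lyz2 10.1-fold, Wfdc17 24.98-fold, the deiodinase gene Dio2 37.2-fold and Mfap5, of elastic fibres, 12.3-fold.

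Proliferation genes were higher in 24 of 25 cases in the IRR300 section, with a median of 0.40 (0.31 to 0.49). Mki67 stood at 41.2 against 58.0 CPM and Top2a at 34.6 against 37.9 CPM. Proximal tubule transport genes were higher in 15 of 15 cases with a median of 0.95 (0.71 to 1.19), and the phosphate carrier Slc34a1 had a ratio of 2.57. Fatty acid oxidation genes were higher in 12 of 15 cases (median 0.45), with Acsm2 at a ratio of 2.04. The tubular injury list was split, 9 genes higher and 9 lower, with a median of 0.10 (-0.21 to 0.57). Its member Havcr1 stood at 294 against 677 CPM, a ratio of 2.31 (2.27 to 2.34), Spp1 at 1.56 and Lcn2 at 0.887, whose log2 ratio of -0.17 turned to 0.06 within tubule segments. Alternative activation genes were lower in 14 of 15 cases (median -2.08), with Arg1 6.66-fold and Mrc1 4.23-fold lower. Thbs1 was 2.61-fold lower (288 against 110 CPM) and Pf4 3.26-fold; Cd47 had a ratio of 0.801 and Cd36 one of 1.59. The thrombospondin axis as a list lay at 0.05 (-1.39 to 0.43).

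Interferon response genes were lower in 14 of 14 cases in the IRR300 section (median -1.14), antigen presentation genes in 12 of 12 (-0.97) and endothelial list genes in 12 of 12 (-1.93). Chemokine genes were lower in 14 of 16 cases (-0.87), with Ccl6 6.64-fold lower, and classical activation genes in 11 of 12 (-1.31). Fibrosis-associated macrophage genes were lower in 10 of 14 (-0.68, -2.58 to 0.64) and coagulation and complement genes in 9 of 15 (-0.41, -1.93 to 1.28). Platelet genes were lower in 5 of 7 (-1.71, -2.25 to 0.49), and these intervals all included 0. The platelet median was the value of Pf4, which macrophage-like cells also carried at 947 and 1168 CPM, so it is no measure of platelets alone. Glycolysis and hypoxia genes were higher in 12 of 14 cases (0.35), with Aldoa at a ratio of 1.40, and the dissociation stress list lay at 0.11. Spots were also compared within the tubule segment whose markers led them, since tubule markers differed between the sections. Matrix genes then had medians of -1.73 in proximal tubule, -1.81 in loop of Henle and -2.07 in collecting duct spots. Proliferation genes had medians of 0.56, 0.38 and 0.29 there, and injury genes in proximal tubule spots were higher in 14 of 18 cases with a median of 0.45 (0.18 to 0.68). The injury medians of loop of Henle spots, 0.34 (-0.38 to 0.71), and collecting duct spots, 0.19 (-0.49 to 0.55), had intervals that included 0, as did the value over the segments, 0.33 (-0.34 to 0.71).

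Regions of the sections were sought by clustering the spots on expression, and co-location asked whether macrophage markers lay with matrix, injury or proliferation genes. Spots fell apart by section, so that region sizes could not be compared between groups. Of 21 regions, 20 had at least 90% of their spots from 1 section, and these held 98.8% of all spots. The largest IRD7 region was led by Ccl8, Igfbp2, Dio2 and Col12a1 with 1058 spots, and another by the macrophage genes Ccl6, Arg1 and Mmp12 with 708. The largest IRR300 regions were led by Slc14a2, Slc12a1 and Umod, of the loop of Henle, with 1056 spots and by Pck1 and Dnase1 with 881. Macrophage markers and matrix genes rose together across spots thinned to 3000 UMIs. Their Spearman correlation was 0.68 (0.66 to 0.69) across IRD7 spots and 0.40 (0.37 to 0.42) across IRR300 spots. The part of tubule RNA in each spot was not taken into account, so spots with less of it were not parted from co-location. Macrophage markers correlated at 0.12 and 0.23 with tubular injury genes and at 0.12 and 0.16 with proliferation genes. Matrix and injury genes correlated at 0.12 and 0.41. Neighbouring spots are not independent, and IRR300 spots held fewer macrophage UMIs, a mean of 3.49 against 18.9 of 3000, which lowers a correlation. Proliferation genes had a mean of only 1.89 and 2.43 UMIs in IRD7 and IRR300 spots, so their correlations cannot be ranked against those of matrix genes.

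Single cells and sections were finally set side by side, since they measure the same contrast on different material. Interferon response, antigen presentation, matrix and endothelial genes were lower in IRR300 material in both, and fatty acid oxidation genes higher. Proliferation genes, Thbs1, Arg1, Mrc1 and Pf4 went opposite ways. Values over all cells include class shares. Matrix genes lay at 0.15 (0.06 to 0.42) within stromal-like cells and the endothelial list at -0.10 (-0.34 to 0.02) within endothelial-like cells. Fatty acid oxidation genes lay at 0.41 in proximal tubule-like cells, a larger part of the IRR300 library, and at -0.06 in macrophage-like cells. Across 13948 genes the log2 ratios of all cells and of the sections had a Spearman correlation of 0.35 (0.33 to 0.36) and a Pearson correlation of 0.33; genes are not independent replicates. The direction was shared by 59.7% of genes, and by 405 of the 448 genes that differed over 2-fold in both. With each cell class given the same weight in both libraries the Spearman correlation was 0.18, the direction was shared by 53.7% of genes, and by 174 of the 223 over 2-fold in both. In all cells Thbs1 stood at 291 against 557 CPM and in the sections at 288 against 110 CPM. The interferon response list lay at -1.69 in all cells and -1.14 in the sections, and the matrix list at -0.78 and -2.14. Spp1 was lower in all cells and higher in the section, at log2 ratios of -0.93 and 0.64.

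**Figure D4:**
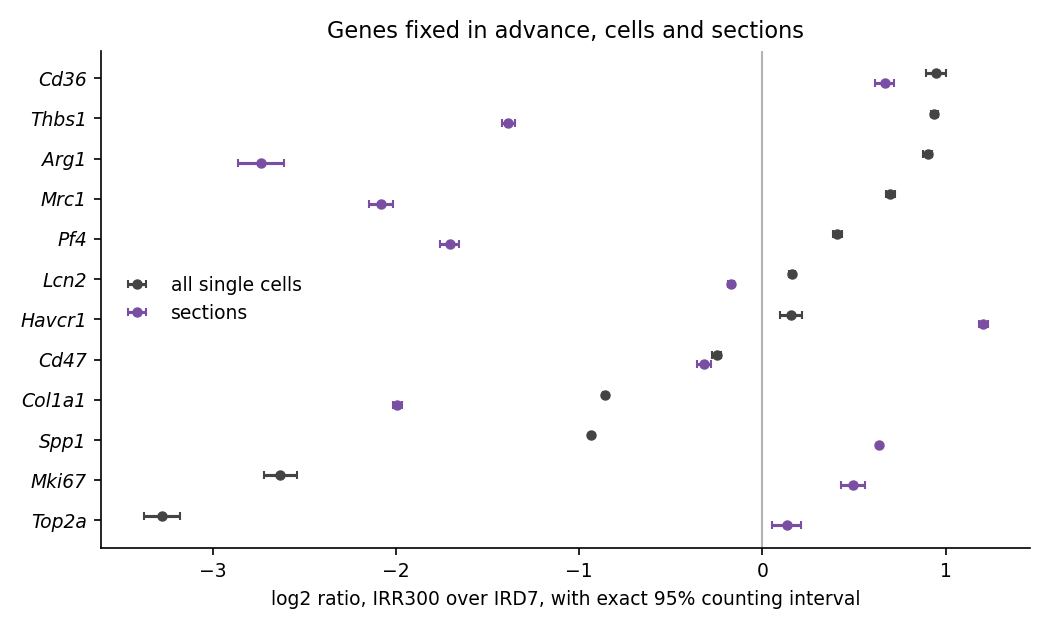
Log2 ratio, IRR300 over IRD7, of the 12 genes fixed in advance (horizontal axis), for counts summed over all single cells and over the spots of the sections; points are ratios and bars exact 95% counting intervals. Thbs1 lay at 0.94 in all cells and at -1.39 in the sections.

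Where the main genes lie in the GRCm38 mouse genome, all as protein-coding genes, was taken from the annotation. Thbs1 (ENSMUSG00000040152) spans positions 118111876 to 118127133 of chromosome 2, Mki67 (ENSMUSG00000031004) 135689784 to 135716361 of chromosome 7 and Top2a (ENSMUSG00000020914) 98992943 to 99024189 of chromosome 11. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042 and Havcr1 (ENSMUSG00000040405) on the same chromosome from 46735080 to 46779578. Gbp2 (ENSMUSG00000028270) lies on chromosome 3 from 142620602 to 142638008, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050 and Ren1 (ENSMUSG00000070645) on chromosome 1 from 133350510 to 133360325.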

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

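Of the tests in this part, those of a drop in every class, of proliferation throughout the tissue, of handling in neutrophil-like cells, of swapped sections and of macrophage loss in the section were chosen only after the results were seen, as were the bounds that decided each test and the Thbs1 ratio at fixed class shares.

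Cells and sections of the same groups lay on opposite sides of no difference for several results, and the difference itself was not tested. Proliferation genes had a median log2 ratio of -2.85 in all cells and 0.40 in the sections, with Mki67 at -2.63 and 0.49 and Top2a at -3.28 and 0.13. Macrophage-linked genes went the other way, higher in IRR300 cells and lower in its section. These were Thbs1 (0.94 and -1.39), Arg1 (0.90 and -2.74), Mrc1 (0.70 and -2.08) and Pf4 (0.41 and -1.71). Lcn2 lay at 0.16 and -0.17, and Spp1 at -0.93 and 0.64. Shares of cell classes, set against their marker genes in the sections, parted too. Macrophage-like cells were slightly more frequent (0.18) while their markers lay at -2.49, neutrophil-like cells lay at 0.87 and -0.83, and podocyte-like cells at 1.57 and -0.97. Loop of Henle-like cells lay at -0.29 against 1.60, collecting duct principal-like cells at -0.64 against 1.44 and urothelium-like cells at -0.79 against 0.62. The erythroid list lay at 10.55 in all cells and -4.37 in the sections.

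Cycling macrophages were fewer in the IRR300 single-cell library. Lower depth per cell was argued against, since the ratio was 0.0504 (0.0303 to 0.0791) with every cell thinned to the same depth. Lower proliferation throughout the tissue predicted a negative section median, but this was 0.40 (0.31 to 0.49). That value argued against it only for the tissue in the sections and could not decide for the kidney, since the sections differed in content. Regions mostly of 1 section held 98.8% of all spots, and macrophage markers lay at -2.49. A drop in cycling cells of every class of that library had its predicted value, a ratio of 0.147 (0.112 to 0.190) outside macrophages, so much of the pattern may not belong to macrophages. That pool includes neutrophils, which lay at background; the ratios of stromal-like cells, 0.114 (0.0539 to 0.216), and T and NK-like cells, 0.136 (0.0430 to 0.333), overlapped the macrophage interval, and that of proximal tubule-like cells, 0.167 (0.0983 to 0.271), lay above it. Platelet depletion, which the design names, stays open and untested with 1 library per group, as do loss of cycling cells in dissociation, differences between single mice and a different time after injury, which the labels do not spell out.

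Thbs1 was higher in IRR300 cells and lower in the IRR300 section. For the cells, shares of cell classes were argued against. Thbs1 had a median log2 ratio of 0.77 over 8 classes, whose values ranged from -0.02 to 1.55. With IRD7 class weights in both libraries its log2 ratio was 1.24, with an interval of 1.21 to 1.26 from simulated counts. For the section, loss of cells that carry Thbs1 may account for the lower level. Macrophage markers lay at -2.49 (-2.73 to -2.07), further down than Thbs1. Macrophages could not be singled out, since fibroblast markers lay at -2.20 and monocyte markers at -1.40 (-2.52 to 0.43). Of 36868 Thbs1 counts in IRD7 cells, macrophage-like cells held 12557, stromal-like cells 9346 and monocyte-like cells 8950. A swap of the section labels was argued against by the positive correlation between cells and sections across genes. It was 0.35 (0.33 to 0.36), or 0.18 (0.16 to 0.20) with equal class weights. The neutrophil-like class held a cluster of 470 IRD7 and 1122 IRR300 cells and one of 287 and 379, so its ratios mix subtypes. Within that limit, a stronger handling response of IRR300 cells was argued against in neutrophil-like cells, where the dissociation stress list lay at -0.69 (-1.06 to -0.40) and Thbs1 at 0.87. It stays open elsewhere, with that list at 0.0036 (-0.24 to 0.25) in all cells, -0.07 (-0.39 to 0.32) in macrophage-like, -0.28 in monocyte-like and 0.79 in proximal tubule-like cells (0.11 in the shared clusters), as do platelet depletion and the time after injury, which were not tested.

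Matrix genes were lower in the IRR300 section. A different mix of tubule segments was argued against, since the median was -1.73 (-1.95 to -1.40) within proximal tubule spots. Non-kidney tissue could not be decided by this test, since every kept spot was given to a segment, fat-led and haemoglobin-led ones included. Regions mostly of 1 section held 98.8% of all spots, so a difference in the tissue sampled was not excluded. For scaling to a total with more mitochondrial RNA, the median was -2.13 (-2.36 to -1.70) with mitochondrial and ribosomal protein genes left out. That test could not decide, since mitochondrial genes held 3.56% of IRD7 and 8.65% of IRR300 UMIs but ribosomal genes 15.7% and 11.2%. Leaving both out moved every gene by only 0.011. Size factors in place of totals, considered after the values were seen, moved every gene by 0.098. This was small beside the section matrix median of -2.14 and argued against scaling as its main source. Fewer stromal cells at a like level per cell could not be decided: the median within stromal-like cells, whose subtypes differed between libraries, was 0.15 (0.06 to 0.42), near no difference but with an upper bound past 0.3, and the stromal share was only 2.09-fold lower, yet in the section pericyte and smooth muscle markers lay at -1.75 (-2.67 to -0.51) and fibroblast markers, some of them matrix genes, at -2.20. Platelet depletion, which the design names, and a different time after injury were not tested and stay open.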

How the results depend on the processing

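The 9 alternatives on subsets of clusters, spots and cycling genes, and the inclusion of interferon and antigen presentation lists here, were chosen only after the data were seen. Over 31 main results, 172 of 189 alternative values stayed within the interval of the reported value, 17 moved and 0 reversed as called results. Among the 31 were the co-location correlations, the correlation of cells with sections and the share of spots in regions mostly of 1 section. These are not differences between the groups, so the counts do not describe group differences alone. All 24 results with an interval on one side of their reference value kept their direction. Of the 7 others 5 did, and proximal tubule transport in its own class and the endothelial list did not. The cycling ratio stayed between 0.0374 and 0.336, the macrophage interferon median between -2.93 and -2.56 and the section matrix median between -2.19 and -1.92. For the values that follow the cause was not tested. The macrophage share ratio was 1.22 with at least 500 genes per cell, 1.07 (0.999 to 1.14) at resolution 2.0 and 1.55 with each library clustered on its own. The cycling ratio was 0.296 with 1 gene asked for, 0.0936 at 2000 UMIs and 0.336 unthinned, which leaves the deeper cells more chances to be called. Macrophage proliferation lay at -2.58 without the proliferation-led cluster, and the endothelial list at 0.11 at resolution 2.0. Section proliferation lay at 0.50 with size factors and proximal tubule transport at 0.65 within segments. Unthinned co-location of macrophage markers was 0.738 and 0.609 with matrix, 0.228 and 0.295 with proliferation and 0.148 and 0.320 with injury genes in IRD7 and IRR300 spots. Agreement was 0.180 with equal class weights. Of 2056 alternative values of 270 named genes and lists, 434 moved and 17 reversed. Reversed with doublets kept were Havcr1 (-0.014) and Slc4a4 (0.0041) of the proximal tubule, stromal Arg1 (0.046) and endothelial Ccl21a (-0.69). With the Havcr1-led cluster added, proximal tubule Havcr1 was -0.054 and Slc4a4 0.022; in the shared clusters only, Havcr1 was -0.80, Slc4a4 0.0064, Lrp2 -0.092, Cd47 0.063 and S100a6 0.18. Lrp2 was -0.061 with size factors, macrophage Spp1 -0.058 without the proliferation-led cluster and section Lcn2 0.058 within segments. At resolution 2.0, endothelial Spp1 was 0.19, Flt1 0.092 and Rsad2 0.064. Fatty acid oxidation in the proximal tubule kept its side, but its interval reached 0 with size factors (0.22) and without mitochondrial and ribosomal genes (0.31). Of the 5 comparisons simulated, endothelial-like cells recovered the fewest 1.5-fold genes (50.7%).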

Other observations

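The contrast of cycling with other macrophages, its genes and the other cell classes of this part were chosen only after the data were seen, and no tests of explanations were made on them.

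As a part of their total RNA, cycling macrophages of the IRD7 library had less RNA of alternative activation and fibrosis-associated genes than the other macrophages beside them. Among 318 cycling and 1648 other macrophage-like cells, Thbs1 was 2.67-fold lower in the cycling ones (631 against 236 CPM, a ratio of 0.374, 0.352 to 0.398). Arg1 was 2.38-fold, Spp1 2.17-fold, Fabp5 2.09-fold, Gpnmb 1.958-fold and Fn1 1.66-fold lower. The chitinase-like gene Chil3 was 4.13-fold and the haemoglobin scavenger receptor Cd163 3.19-fold lower. Little difference was seen in the monocyte chemokine receptor Ccr2 (0.989, 0.925 to 1.06), the complement gene C1qa (0.943) and Cd36 (1.02), and the metalloproteinase gene Mmp12 was higher (1.15). Alternative activation genes had a median log2 ratio of -0.78 with 1 of 15 higher, and fibrosis-associated macrophage genes one of -0.62 with 2 of 14 higher. Proximal tubule transport genes were lower too, in 15 of 15 cases with a median of -0.47 (-0.64 to -0.37). Cycling cells had a median of 14249.5 UMIs against 10183.5, and these larger totals were not parted from lower levels of the genes. Classical activation genes lay at 0.03 with 7 of 13 higher, fatty acid oxidation genes at -0.14 (-0.38 to 0.10) and antigen presentation genes at 0.37 (-0.08 to 0.51). The 20 IRR300 macrophages called cycling, a share of 0.815% near the neutrophil background of 0.470%, so that false calls among them were not excluded, had Thbs1 at 816 CPM against 1615 in the others, but more Spp1 (6587 against 4606 CPM) and Arg1 (1909 against 1595 CPM).

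Blood-borne cells shared the lower interferon genes. In monocyte-like cells all 14 interferon response genes were lower in the IRR300 library (median -3.27), with Gbp2 227-fold lower (837 against 3.69 CPM), and chemokine genes were lower in 14 of 16 cases (-1.38), with Ccl4 5.48-fold lower. Thbs1 stood at 1442 against 2835 CPM in these cells, the highest level among the 8 classes. In neutrophil-like cells interferon genes had a median of -2.03 and dissociation stress genes were lower in 14 of 14 cases (-0.69). Lcn2, a neutrophil granule gene, stood there at 1180 against 2860 CPM, a ratio of 2.42, and Il1b at 7609 against 5957 CPM. T and NK-like cells had interferon genes at -1.19 and proliferation genes at -2.54, and the chemokine gene Ccl5 was 2.22-fold lower. That class differed in make-up, as its NK cell cluster held 53 IRD7 and 9 IRR300 cells and its T cell cluster led by Hist1h2ap 57 and 3. In loop of Henle-like cells the medians were -2.29 for interferon and -2.30 for proliferation genes.

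Haemoglobin RNA was nearly missing from the IRD7 cells. Hbb-bs had 8 counts there and 15585 in IRR300 cells, and Hba-a1 4 against 7011, while Alas2, a haem synthesis gene of red cell precursors, had 54 against 78. In IRR300 cells Hbb-bs was found in classes that do not make it, at 265 CPM in proximal tubule-like and 226 CPM in neutrophil-like cells. The sections went the other way, with Hbb-bs at 977 CPM in IRD7 and 47.2 CPM in IRR300. Red cells were lysed before capture per the labels, the remaining blood of each sample was not measured, and a different treatment of haemoglobin reads in the libraries was not excluded.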
